A study of Mus musculus with 12 samples.

How the data were processed

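The series holds 12 mouse liver RNA-seq libraries, 3 in each of 4 groups formed by genotype (iAMPK or L-iAMPK) and doxycycline. Per the labels' protocols, RNA from flash-frozen liver was extracted with the Zymo Quick-RNA MiniPrep kit and libraries were made with the TruSeq stranded-mRNA kit. FastQC, STAR 2.4.0k, HOMER and edgeR 3.6.8 and the build mm10 are named in the submitters' processing notes, which give them no role or order, and whether counting used the strand is not given in the sources used here.

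The authors deposited FPKM per gene and library, and the values show that they had added 0.5 to each, which was subtracted before use. A second deposited table holds a signal of tags per gene scaled to a common total per library, with the library totals per the file headers, and the log2 fold changes and adjusted p-values of the authors' own comparisons. Both tables list 24453 genes, and 20243 genes have the same transcript in both and 4210 have another. In the name column 26 symbols had been turned into dates, and gene symbols were taken from the annotation field instead. Coordinates are those of the deposited tables.

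The design had provided for counts or FPKM, and FPKM was the unit for the main test. Genes with an FPKM of at least 0.5 in at least 3 of the 12 libraries were kept (12614), and log2(FPKM + 0.5) was fitted with limma 3.58.1 in R 4.3.3 with 4 group means over all libraries, an intensity trend and a robust empirical Bayes step. Benjamini-Hochberg adjustment covered all genes tested, with a threshold of 0.05. The comparisons were doxycycline in L-iAMPK, genotypes on doxycycline, doxycycline in iAMPK, genotypes without doxycycline, the interaction of genotype and doxycycline, and the genes called in both comparisons with active AMPK.

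The scaled tags gave whole reads when divided by the value of 1 read in each library, 100% of values lying within 0.02 of a whole number of reads (largest deviation 0.00616). For iAMPK HFD+dox replicate 2, where 1 read is worth 0.995 scaled tags, this cannot be distinguished from whole tags and its reads were not claimed. The remaining 11 libraries were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr) as an alternative added after seeing the data, which called 2992 genes for doxycycline in L-iAMPK among 13773 tested. The precision of each level is the spread of 3 libraries, and the depth was 13569437 to 20696899 recovered reads per library.

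On data simulated for the 12614 genes tested, with 67, 67 and 66 genes changed by log2 0.5, 1 and 2, limma recovered 53.7%, 85.1% and 97.0% of them for doxycycline in L-iAMPK, with 9 false calls. It recovered 53.7%, 82.1% and 97.0% for genotypes on doxycycline and 20.9%, 68.7% and 93.9% for the interaction, with 6 and 4 false calls, and made 0 calls with no effect.

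In all, 29 gene lists were fixed: AMPK subunits and upstream kinases, metabolic pathways, stress and signalling responses, cell type markers, liver zones, proliferation, markers of other tissues and sex-biased genes. Lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it. Camera ranks a list against all other genes, so a list can be called up with a median below 0. Measured members were counted over all genes tested and adjusted over the list alone. The groups, the tests, the lists, the rule for named genes and the alternatives were chosen before the data were examined.

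The genes named were the AMPK subunit genes, and in each comparison with active AMPK and in the interaction, the 10 largest increases and the 10 largest decreases among genes with an adjusted p under 0.05, a mean of at least 1 FPKM and groups that do not overlap (10% of genes would by chance, 3 against 3). Control comparisons took 5 and 5. In a list, up to 4 members with the smallest p were named, and the 3 genes with the smallest p where none was called. Symbols starting with Gm or LOC and a digit, ending in Rik or starting with Mir or Snor were left out. Genes of the chromosome 11 region were chosen after their values were seen. Single values of some genes under this rule are not reported here.

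The alternatives were median-ratio scaling, quantile normalization, pseudocounts of 0.1 and 1, no filter, a filter at 2 FPKM, array weights, a replicate block, limma without the trend and robust step, a log2 change of at least 1 as well, only the compared libraries, and leaving out each library in turn. For lists they were an estimated correlation, fry, median-ratio scaling, the block and leaving out libraries. Counts of list members after median-ratio scaling, list tests after quantile normalization and the AMPK list without Prkaa1 were added after seeing the data.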

Results

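Liver RNA was measured by stranded mRNA sequencing in C57Bl/6J mice fed a diet with 45% of its calories from fat for 8 weeks. iAMPK mice carried a doxycycline-inducible transgene of the AMPK α1 subunit together with the rtTA activator, and L-iAMPK mice carried Albumin-Cre as well, which is active in hepatocytes. Each genotype was studied with and without doxycycline (dox), giving 4 groups of 3 libraries: iAMPK HFD, iAMPK HFD+dox, L-iAMPK HFD and L-iAMPK HFD+dox. AMPK is a kinase that senses cellular energy, and per the labels it was active only in L-iAMPK HFD+dox. Between 13569437 and 20696899 reads per library lay in genes. Among the 11 libraries with recovered reads, every pair within a group differed by more than sampling noise (lowest chi-square per degree of freedom 7.93). The p-values measure the spread between these samples, part of which may be technical.

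Levels are mean FPKM ± SD with n = 3 per group, and changes are log2 fold changes ± SE on the log2(FPKM + 0.5) scale, which understates the change of low genes. Genes are said to have risen or fallen where limma's adjusted p over 12614 genes was under 0.05. Coordinates are mm10.

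Prkaa1, which encodes the α1 subunit supplied by the transgene (chromosome 15, 5143861 to 5181899), stood at 1071 ± 170.1 FPKM in L-iAMPK HFD+dox. It stood at 3.34 ± 0.749 in iAMPK HFD, 2.85 ± 0.214 in iAMPK HFD+dox and 3.51 ± 0.343 in L-iAMPK HFD, and gene-level FPKM cannot separate the transgene from the endogenous gene. Its rise was 8.05 ± 0.14 against L-iAMPK HFD (limma adjusted p = 3.96e-11) and 8.31 ± 0.14 against iAMPK HFD+dox (adjusted p = 2.78e-11). Prkaa2, the other catalytic subunit, also rose in L-iAMPK HFD+dox, to 11.9 ± 1.04 FPKM, by 0.47 ± 0.11 (adjusted p = 0.0111) and 0.59 ± 0.11 (adjusted p = 0.00573) in the same comparisons. The regulatory subunit gene Prkag2 changed by -0.43 ± 0.07 against L-iAMPK HFD (adjusted p = 0.00237) and by -0.26 ± 0.07 against iAMPK HFD+dox (adjusted p = 0.0318). The second of these calls ended after median-ratio scaling (adjusted p = 0.0665) or quantile normalization (0.0598), in a fit of only the compared libraries (0.0891) and by edgeR on recovered reads, a test added after seeing the data (0.181). It also ended without L-iAMPK HFD+dox replicate 1 (0.0559), 2 (0.0889) or 3 (0.0865) or iAMPK HFD+dox replicate 2 (0.0744) or 3 (0.111). Prkab1 rose against L-iAMPK HFD by 0.37 ± 0.11 (adjusted p = 0.0259), a call that ended without L-iAMPK HFD replicate 1 (0.0627) or 2 (0.0823) or L-iAMPK HFD+dox replicate 2 (0.0529) and in a fit of only the compared libraries (0.0674). Its difference from iAMPK HFD+dox was 0.19 ± 0.11, adjusted p = 0.235. Prkab2 and Prkag1 did not pass in either comparison (adjusted p = 0.117 and 0.111 against L-iAMPK HFD, 0.999 and 0.118 against iAMPK HFD+dox), although Prkag1 passed in both after median-ratio scaling (adjusted p = 0.0167 and 0.0424) and quantile normalization (adjusted p = 0.0180 and 0.0410). Against L-iAMPK HFD, Prkag1 passed by edgeR (adjusted p = 0.0183) and Prkab2 with array weights (adjusted p = 0.0155).

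The first comparison asked how livers with active AMPK differed from livers of the same genotype without doxycycline. With doxycycline, L-iAMPK livers had more Muc13, a transmembrane mucin (chromosome 16, 33794037 to 33819927), which stood at 25.3 ± 5.11 FPKM against 0.0403 ± 0.0304 without doxycycline, a change of 5.56 ± 0.14, adjusted p = 7.19e-10. Cux2, a homeodomain transcription factor, rose from 0.0683 ± 0.00839 to 4.25 ± 1.65 FPKM, the cytochrome P450 gene Cyp2c29 from 190.2 ± 56.4 to 1153 ± 207, and Csad, an enzyme of taurine synthesis, from 46.7 ± 12.4 to 240.0 ± 36.1 (log2 2.62 and 2.37 for the latter pair, limma adjusted p = 2.6e-05, 2.6e-05 and 0.000207 for the 3 in turn). Acsf2, an acyl-CoA synthetase (chromosome 11, 94557102 to 94601786), fell from 39.6 ± 5.23 to 1.73 ± 0.341 FPKM, and Abcc3, an exporter of organic anions (chromosome 11, 94343295 to 94392976), from 48.9 ± 10.4 to 3.79 ± 0.521 (-4.17 ± 0.13 and -3.51 ± 0.15, adjusted p = 9.71e-09 and 2.68e-07). The carboxylesterase gene Ces1g fell from 69.6 ± 19.5 to 4.04 ± 0.528, and Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, from 51.1 ± 21.7 to 3.16 ± 0.306 FPKM (-3.92 ± 0.17 and -3.71 ± 0.75, adjusted p = 3.06e-07 and 0.00776).

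Other large rises in this comparison were Cyp2a4 (4.87 ± 0.91), Serpina4-ps1 (3.93 ± 1.17), Mup17 (3.73 ± 1.02), Mup9 (2.99 ± 0.72) and Cabp2 (2.28 ± 0.29), with limma adjusted p = 0.00555, 0.0339, 0.0253, 0.0150 and 0.000643. Further large falls were Ly6d (-4.14 ± 1.05), Sprr1a (-3.75 ± 0.70), Ubd (-3.22 ± 0.70), Ifi27l2b (-3.18 ± 0.59), Cidec (-3.08 ± 0.82) and Ttc39aos1 (-2.84 ± 0.46), with adjusted p = 0.0183, 0.00551, 0.0103, 0.00551, 0.0219 and 0.00285. Members of the Mup, Serpina, Cyp2a, Cyp2c and Ces1 families share reads with near-identical copies, so their single values are uncertain. Of these 20 genes, Ly6d, Cidec, Mup9, Mup17 and Serpina4-ps1 lost the call when a library was left out. The counts were 5, 4 and 1 without L-iAMPK HFD replicates 1 to 3 (up to 0.0960, 0.0905 and 0.0570). For L-iAMPK HFD+dox they were 4, 1 and 4 (up to 0.107, 0.0596 and 0.0920). By edgeR on recovered reads, the calls of Mup17 and Serpina4-ps1 ended (adjusted p = 0.0529 and 0.0573), and a pseudocount of 1 ended that of Serpina4-ps1 (adjusted p = 0.0541).

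**Figure D1:**
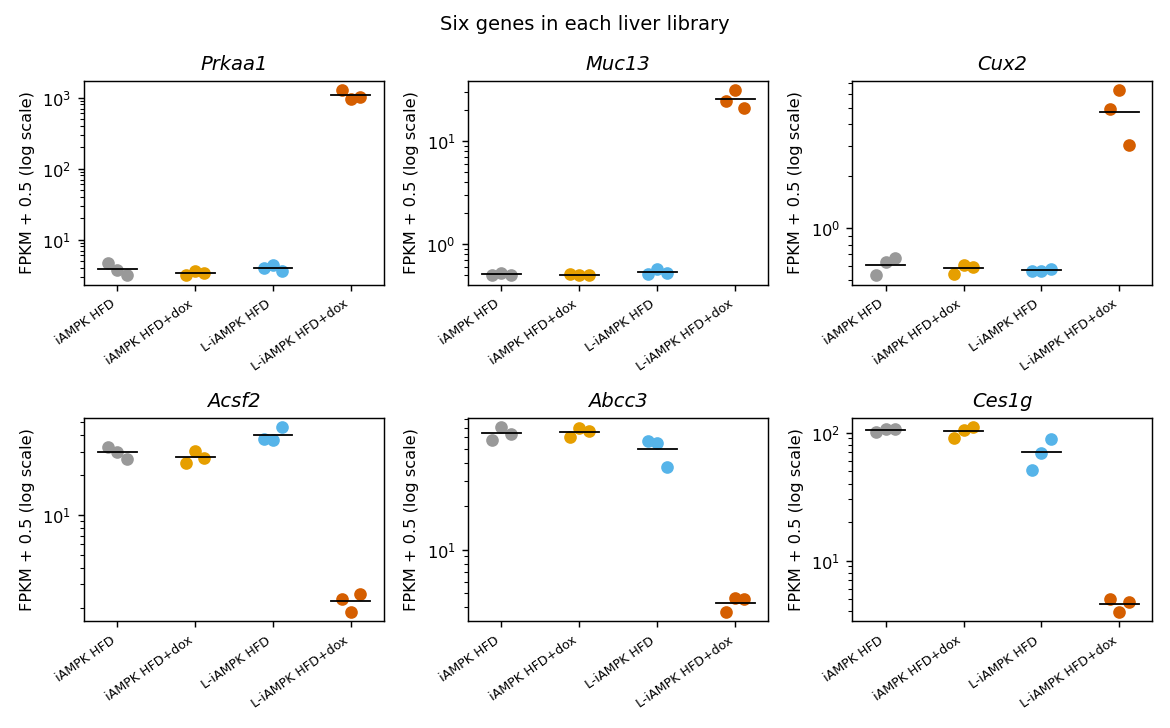
FPKM + 0.5 on a log axis for Prkaa1, Muc13, Cux2, Acsf2, Abcc3 and Ces1g in the 4 groups; each point is a library and each line the mean of 3 libraries. Prkaa1, Muc13 and Cux2 lie highest, and Acsf2, Abcc3 and Ces1g lowest, in L-iAMPK HFD+dox.

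Genes of sterol synthesis and fatty acid oxidation that passed fell with doxycycline in L-iAMPK livers. In the list of cholesterol synthesis and uptake genes, 15 fell and 9 did not pass of 24, and 16 fell when adjusted over the list alone. The cholesterol list had median log2 -0.96, camera adjusted p = 3.38e-05 (down, adjusted p = 0.548 with estimated correlation). Mvk, which encodes mevalonate kinase, changed by -1.48 ± 0.15, adjusted p = 0.000167, and the sterol synthesis genes Msmo1 and Idi1 by -1.51 ± 0.25 and -0.94 ± 0.16. Among fatty acid oxidation and PPAR-alpha target genes, 17 fell and 11 did not pass of 28, 1 rose and 14 fell after median-ratio scaling, and 18 fell when adjusted over the list alone. The fatty acid oxidation list had median log2 -0.45, camera adjusted p = 0.000155 (down, adjusted p = 0.548 with estimated correlation). They included the mitochondrial enzymes Acadl (-0.62 ± 0.07) and Bdh1 (-0.86 ± 0.10). Among lipid droplet and PPAR-gamma target genes, 8 fell and 11 did not pass of 19, also when adjusted over the list alone. The lipid droplet list had median log2 -0.69, camera adjusted p = 0.0266 (down, adjusted p = 0.548 with estimated correlation). Members included the triglyceride lipase Pnpla2 at -0.66 ± 0.12 and Mogat1 at -2.17 ± 0.44. That list was not called without L-iAMPK HFD replicate 2 (adjusted p = 0.0542) or L-iAMPK HFD+dox replicate 3 (0.0599). For fatty acid and triglyceride synthesis, 5 rose, 4 fell and 15 did not pass of 24, and 6 rose and 5 fell when adjusted over the list alone, with Thrsp (1.28 ± 0.20), Mlxipl (0.60 ± 0.12) and Dgat2 (0.50 ± 0.11) higher and Aacs (-0.88 ± 0.17) lower. The synthesis list was not called (camera adjusted p = 0.0855, adjusted p = 0.655 with estimated correlation), and its median (-0.06) and mean (-0.13) lay below 0 while camera pointed up. It was called up without L-iAMPK HFD replicate 1 (adjusted p = 0.0470), L-iAMPK HFD replicate 2 (0.0135), L-iAMPK HFD+dox replicate 1 (0.0348) or L-iAMPK HFD+dox replicate 3 (0.0321).

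For gluconeogenesis and glucose handling, 3 rose, 4 fell and 13 did not pass of 20, also when adjusted over the list alone, and 4 rose and 1 fell after median-ratio scaling. The gluconeogenic enzyme Fbp1 rose by 0.92 ± 0.11 and liver glycogen phosphorylase, Pygl, by 0.57 ± 0.08 (limma adjusted p = 0.000541 and 0.00128), while the list was not called (camera adjusted p = 0.0723, adjusted p = 0.548 with estimated correlation), with its median at -0.02 and its mean at 0.07. It was called without L-iAMPK HFD replicate 3 (adjusted p = 0.0415). Of the bile acid synthesis and transport genes, 3 rose, 1 fell and 14 did not pass of 18, also when adjusted over the list alone, and the list was called up (camera adjusted p = 0.00613, adjusted p = 0.548 with estimated correlation), a call that ended after quantile normalization (adjusted p = 0.223). The bile acid uptake transporter Slc10a1 rose by 1.01 ± 0.13 and the export pump Abcb11 by 0.53 ± 0.07, and the phospholipid transporter Abcb4 was lower (-0.66 ± 0.11). In the lysosome and autophagy list, 13 fell and 21 did not pass of 34, 1 rose and 5 fell after median-ratio scaling, and 15 fell when adjusted over the list alone. The lysosome list had median log2 -0.29, camera adjusted p = 0.00957 (down, adjusted p = 0.548 with estimated correlation). Members included Hexa at -0.86 ± 0.16. For nuclear-encoded oxidative phosphorylation, 1 rose, 3 fell and 51 did not pass of 55, 10 rose after median-ratio scaling, and 2 fell when adjusted over the list alone. Sdhc (-0.27 ± 0.06) and Uqcrc1 (-0.30 ± 0.07) were among those that fell. Median-ratio scaling ended the calls of Sdhc and Uqcrc1 (adjusted p = 0.152 and 0.143), as did edgeR (adjusted p = 0.305 and 0.273). The list's median and mean were both -0.01, camera called it up (camera adjusted p = 0.0346, adjusted p = 0.583 with estimated correlation), and fry pointed down (adjusted p = 0.715). That call ended after quantile normalization (adjusted p = 0.485) and without L-iAMPK HFD replicate 1 (adjusted p = 0.130), L-iAMPK HFD replicate 2 (0.0589), L-iAMPK HFD+dox replicate 1 (0.0861) or L-iAMPK HFD+dox replicate 2 (0.113).

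Among NRF2 antioxidant targets, 10 fell and 9 did not pass of 19, 1 rose and 10 fell after median-ratio scaling, and 1 rose and 13 fell when adjusted over the list alone (camera adjusted p = 0.00407, adjusted p = 0.548 with estimated correlation), including the glutathione transferase genes Gsta4 (-1.33 ± 0.17) and Gstm1 (-1.22 ± 0.20), which share reads with relatives, and Ugdh (-1.08 ± 0.17). For xenobiotic metabolism, 1 rose, 11 fell and 9 did not pass of 21, 1 rose and 5 fell after median-ratio scaling, and 1 rose and 12 fell when adjusted over the list alone, and the list was not called (camera adjusted p = 0.0839, adjusted p = 0.548 with estimated correlation), with the receptor gene Nr1i3 (CAR) at -1.18 ± 0.16. It was called down after median-ratio scaling (adjusted p = 0.0108), quantile normalization (0.00278) and without L-iAMPK HFD replicate 1 (adjusted p = 0.0243). For the integrated stress response, 2 rose, 4 fell and 17 did not pass of 23, also when adjusted over the list alone, and 2 rose and 2 fell after median-ratio scaling. The integrated stress list had median log2 -0.16, camera adjusted p = 0.936 (down, adjusted p = 0.959 with estimated correlation). Members included the mitochondrial protease Lonp1 at -0.39 ± 0.06 and Atf5 at 0.67 ± 0.14. The endoplasmic reticulum stress list was called up (camera adjusted p = 0.00415, adjusted p = 0.548 with estimated correlation), while 0 of its 20 measured members passed in limma (3 at an unadjusted p under 0.05, 2 by edgeR) and 2 rose after median-ratio scaling. For immediate-early genes, 4 fell and 10 did not pass of 14, and 5 fell when adjusted over the list alone. The immediate-early list had median log2 -0.82, camera adjusted p = 0.0461 (down, adjusted p = 0.548 with estimated correlation). Members included Egr1 at -1.07 ± 0.19 and Klf6 at -1.29 ± 0.26, and this call ended without L-iAMPK HFD replicate 3 (adjusted p = 0.116), L-iAMPK HFD+dox replicate 1 (0.0591) or L-iAMPK HFD+dox replicate 3 (0.0587). In the acute-phase list, 6 rose, 7 fell and 9 did not pass of 22, also when adjusted over the list alone. The fibrinogen genes Fgb, Fga and Fgg rose by 1.13 ± 0.14, 1.07 ± 0.15 and 1.05 ± 0.15, and Il1rn was lower (-1.48 ± 0.26). That list's median (-0.13) and mean (-0.39) lay below 0 while camera pointed up without a call (camera adjusted p = 0.0535, adjusted p = 0.548 with estimated correlation), except without L-iAMPK HFD replicate 2 (adjusted p = 0.0364) or L-iAMPK HFD+dox replicate 1 (0.0215). For the circadian clock, 2 rose, 4 fell and 13 did not pass of 19, and 2 rose and 5 fell when adjusted over the list alone, with Per2 at -1.23 ± 0.23 and Clock at 0.62 ± 0.12 (camera adjusted p = 0.788, adjusted p = 0.900 with estimated correlation).

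Matrix, endothelial and macrophage markers that passed fell with doxycycline in L-iAMPK livers, except 1 matrix marker, and hepatocyte markers that passed rose. Of the extracellular matrix and hepatic stellate cell markers, 1 rose, 22 fell and 11 did not pass of 34, and 1 rose and 28 fell when adjusted over the list alone. The matrix list had median log2 -0.78, camera adjusted p = 3.38e-05 (down, adjusted p = 0.548 with estimated correlation). Lrat, which esterifies retinol for storage in stellate cells, changed by -1.57 ± 0.22, adjusted p = 0.00132, and the basement membrane collagens Col4a2 and Col4a1 by -1.49 ± 0.23 and -1.49 ± 0.28. For liver sinusoidal endothelial markers, 10 fell and 6 did not pass of 16, also when adjusted over the list alone, and 4 fell after median-ratio scaling. The endothelial list had median log2 -0.42, camera adjusted p = 0.00957 (down, adjusted p = 0.548 with estimated correlation). Members included Pecam1 at -0.58 ± 0.11 and Oit3 at -0.62 ± 0.12. For macrophage and Kupffer cell markers, 6 fell and 25 did not pass of 31, also when adjusted over the list alone. The macrophage list had median log2 -0.65, camera adjusted p = 0.0280 (down, adjusted p = 0.655 with estimated correlation). Members included Mmp12 at -2.51 ± 0.54 and Clec7a at -1.58 ± 0.36. The macrophage call ended without L-iAMPK HFD replicate 1 (adjusted p = 0.0756), L-iAMPK HFD replicate 2 (0.0542) or L-iAMPK HFD+dox replicate 1 (0.267). For hepatocyte markers, 13 rose and 11 did not pass of 24, also when adjusted over the list alone. The hepatocyte list had median log2 0.33, camera adjusted p = 6.07e-08 (up, adjusted p = 0.264 with estimated correlation). Members included the apolipoprotein gene Apoc3 at 0.60 ± 0.12. Quantile normalization ended the list's call (adjusted p = 0.138) and that of Apoc3 (adjusted p = 0.129). Among proliferation genes, 11 fell and 6 did not pass of 17, and 12 fell when adjusted over the list alone. The proliferation list had median log2 -0.73, camera adjusted p = 0.00415 (down, adjusted p = 0.548 with estimated correlation). Members included Ccnd1, which encodes cyclin D1, at -2.04 ± 0.33 and Birc5 at -1.12 ± 0.17. For the interferon response, 8 fell and 16 did not pass of 24, 4 fell after median-ratio scaling, and 11 fell when adjusted over the list alone. The interferon list had median log2 -0.69, camera adjusted p = 0.00531 (down, adjusted p = 0.583 with estimated correlation). Members included the immunoproteasome gene Psmb9 at -0.75 ± 0.12, and this call ended without L-iAMPK HFD+dox replicate 1 (adjusted p = 0.0685).

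For cholangiocyte markers, 1 rose, 3 fell and 6 did not pass of 10, and 1 rose and 5 fell when adjusted over the list alone. The cholangiocyte list had median log2 -0.64, camera adjusted p = 0.126 (down, adjusted p = 0.548 with estimated correlation). Median-ratio scaling gave it a call (adjusted p = 0.0415). Members included Krt23 at -2.07 ± 0.17. For pericentral hepatocyte genes, 4 fell and 14 did not pass of 18, also when adjusted over the list alone, and 1 rose and 3 fell after median-ratio scaling. The pericentral list had median log2 -0.17, camera adjusted p = 0.664 (down, adjusted p = 0.887 with estimated correlation). Members included the ammonium transporter Rhbg at -2.17 ± 0.21 and Oat at -1.44 ± 0.24. Periportal hepatocyte genes were called up (camera adjusted p = 0.00957, adjusted p = 0.548 with estimated correlation): 2 rose, 2 fell and 13 did not pass of 17, also when adjusted over the list alone, and 2 rose and 1 fell after median-ratio scaling, with Hal, which degrades histidine, at 1.03 ± 0.21. The sex-biased liver genes were also called up (camera adjusted p = 0.0311, adjusted p = 0.548 with estimated correlation): 1 rose, 1 fell and 13 did not pass of 15, 2 rose after median-ratio scaling, and 1 rose when adjusted over the list alone, with Cyp2d9 at 1.80 ± 0.40. Median-ratio scaling ended both calls (adjusted p = 0.112 and 0.217), as did quantile normalization (adjusted p = 0.512 and 0.333). The periportal call also ended without L-iAMPK HFD replicate 1 (adjusted p = 0.0756), and the sex-biased one without L-iAMPK HFD replicate 2 (adjusted p = 0.0514) or L-iAMPK HFD+dox replicate 1 (0.0861). For lymphocyte and natural killer cell markers, 2 fell and 5 did not pass of 7, also when adjusted over the list alone, and 1 fell after median-ratio scaling. The lymphocyte list had median log2 -0.26, camera adjusted p = 0.643 (down, adjusted p = 0.884 with estimated correlation). In the neutrophil list, 1 fell and 4 did not pass of 5, also when adjusted over the list alone (camera adjusted p = 0.328, adjusted p = 0.655 with estimated correlation), the gene being Lcn2. For markers of blood, pancreas and fat tissue, 1 rose and 9 did not pass of 10, also when adjusted over the list alone (camera adjusted p = 0.188, adjusted p = 0.548 with estimated correlation), the gene being Cela1. The list of AMPK subunits and upstream kinases was called up (camera adjusted p = 0.00119, adjusted p = 0.290 with estimated correlation): 4 rose, 1 fell and 3 did not pass of 8, also when adjusted over the list alone. It holds Prkaa1, raised by the transgene. Of the other 7 members 3 rose and 1 fell, with a median of 0.15 and camera adjusted p = 0.0381 (0.548 with an estimated correlation, 0.0821 after median-ratio scaling).

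In all, 600 genes rose and 2659 fell with doxycycline in L-iAMPK livers (limma). The median log2 change of all genes was -0.13, and after median-ratio scaling 1440 rose and 1406 fell, 2006 of the calls being shared with the same direction. The 50 most abundant genes took 43.3% ± 1.44 (SD, n = 3) of all FPKM in L-iAMPK HFD+dox, 39.7% ± 0.739 in L-iAMPK HFD, 39.6% ± 1.16 in iAMPK HFD and 39.7% ± 1.49 in iAMPK HFD+dox. The total of 3259 calls was 1874 without L-iAMPK HFD replicate 1, 1900 without L-iAMPK HFD replicate 2 and 2170 without L-iAMPK HFD+dox replicate 2, and it was 5390 with array weights and 423 with a log2 change of at least 1 as well. The authors' table has 2666 called genes for these groups (cutoff not given here), 1043 higher and 1623 lower with doxycycline. Of these, 2323 were tested and 1730 called here in the same direction. None of the camera calls in any comparison held with an estimated correlation.

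**Figure D2:**
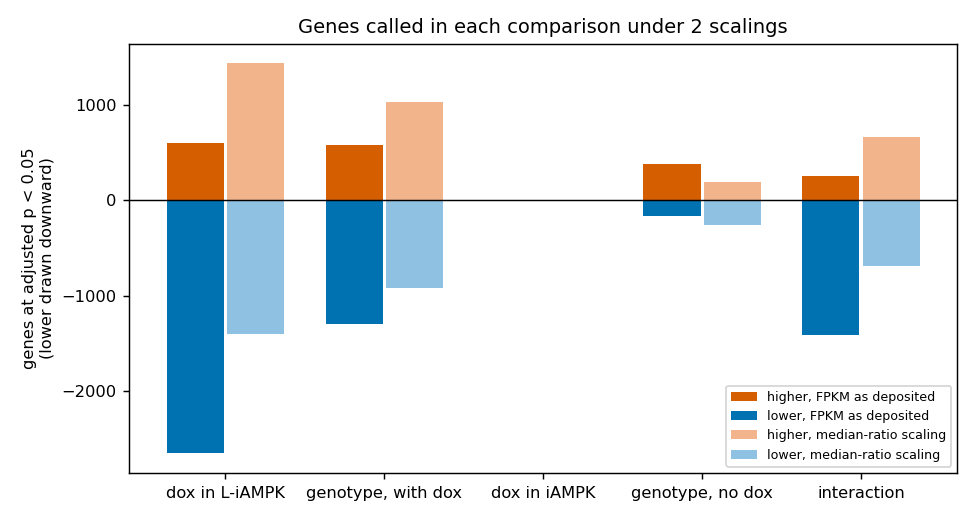
Number of genes called higher (up) and lower (down) in each comparison by limma, with FPKM as deposited and after median-ratio scaling. With doxycycline in L-iAMPK livers the split moved from 600 higher and 2659 lower to 1440 and 1406.

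The second comparison set L-iAMPK HFD+dox against iAMPK HFD+dox, which shares the doxycycline but lacks Albumin-Cre. Besides Prkaa1, Muc13 (5.65 ± 0.14, adjusted p = 6e-10), Cux2 (2.97 ± 0.22, adjusted p = 2.97e-05) and Csad (2.60 ± 0.23, adjusted p = 0.000124) were higher in L-iAMPK HFD+dox, as was Cabp2 (2.53 ± 0.29). Thrsp, a regulator of lipogenesis, stood at 1185 ± 247 FPKM against 260.1 ± 54.0 (2.19 ± 0.20, limma adjusted p = 0.000117), and the glutathione transferase gene Gstm5 at 49.2 ± 7.61 against 9.11 ± 1.75 (2.38 ± 0.13, adjusted p = 2.25e-06). Cyp2a4 (6.60 ± 0.91) and the phosphate transporter gene Slc34a2 (2.16 ± 0.37) were higher too. Lower were Cyp3a11, a drug-metabolizing cytochrome P450, at 13.6 ± 13.2 FPKM against 253 ± 60.2 (-4.57 ± 0.73, adjusted p = 0.00379), Ces1g (-4.50 ± 0.17, adjusted p = 6.93e-08), Abcc3 (-3.93 ± 0.15, adjusted p = 6.93e-08) and Acsf2 (-3.62 ± 0.13, adjusted p = 4.81e-08). Ces1b (-3.29 ± 0.22), Lcn2 (-3.79 ± 0.75), Saa2 (-3.46 ± 0.59), Mup20 (-3.08 ± 0.56) and Ubd (-3.25 ± 0.70) were lower as well, with adjusted p = 2.38e-05, 0.0104, 0.00555, 0.00679 and 0.0146. Pnpla3 was higher (2.49 ± 0.70, adjusted p = 0.0394) and Selenbp2 lower (-3.92 ± 1.09, adjusted p = 0.0391). With a library left out, calls ended among Pnpla3, Selenbp2 and Ubd. The counts were 1, 2 and 2 without L-iAMPK HFD+dox replicates 1 to 3 (up to 0.0741, 0.108 and 0.0824). For iAMPK HFD+dox they were 2, 3 and 2 (up to 0.0883, 0.0898 and 0.0854). By edgeR the calls of Pnpla3 and Selenbp2 ended (adjusted p = 0.121 and 0.0980), as they did with no filter on low values (adjusted p = 0.0518 and 0.0516). A pseudocount of 1 ended that of Selenbp2 (adjusted p = 0.0522), and a fit of only the compared libraries those of Pnpla3 and Ubd (adjusted p = 0.0601 and 0.0522). Values of Cyp2a, Cyp3a, Ces1, Saa, Mup, Selenbp and Gstm genes are uncertain, since close relatives share their reads.

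Respiratory chain genes that passed were higher in L-iAMPK HFD+dox than in iAMPK HFD+dox: in the nuclear-encoded oxidative phosphorylation list 16 rose and 39 did not pass of 55, and 19 rose when adjusted over the list alone. The oxidative phosphorylation list had median log2 0.16, camera adjusted p = 2.82e-12 (up, adjusted p = 0.419 with estimated correlation). The cytochrome c oxidase subunits Cox5b and Cox8a rose by 0.45 ± 0.07 and 0.59 ± 0.11 and the complex I subunit Ndufb8 by 0.41 ± 0.07. In the fatty acid and triglyceride synthesis list, 6 rose and 18 did not pass of 24, and 6 rose and 1 fell when adjusted over the list alone. The lipid synthesis list had median log2 0.34, camera adjusted p = 0.000592 (up, adjusted p = 0.689 with estimated correlation). Members included Dgat2, which makes triglycerides, at 0.73 ± 0.11 and pyruvate kinase, Pklr, at 1.25 ± 0.25. Both lists were also called up between the genotypes without doxycycline (camera adjusted p = 0.00323 and 0.0105, both at adjusted p = 0.519 with an estimated correlation), but not without L-iAMPK HFD replicate 3 (adjusted p = 0.112) and L-iAMPK HFD replicate 2 (adjusted p = 0.120) respectively. In the interaction the lipid synthesis list was not called (camera adjusted p = 0.204, adjusted p = 0.710 with estimated correlation) except without L-iAMPK HFD replicate 2 (adjusted p = 0.0404), and its median (-0.25) lay opposite to camera's direction, up. For cholesterol synthesis and uptake, 1 rose, 3 fell and 20 did not pass of 24, and 1 rose and 4 fell when adjusted over the list alone. The cholesterol list had median log2 -0.50, camera adjusted p = 0.0111 (down, adjusted p = 0.851 with estimated correlation). Members included Mvk at -0.96 ± 0.15 and Ebp at -0.51 ± 0.09. For fatty acid oxidation and PPAR-alpha targets, 2 rose, 9 fell and 17 did not pass of 28, also when adjusted over the list alone, and 2 rose and 4 fell after median-ratio scaling, with Bdh1 at -0.70 ± 0.10, and the list was not called (camera adjusted p = 0.434, adjusted p = 0.868 with estimated correlation). Among NRF2 targets, 6 fell and 13 did not pass of 19, and 1 rose and 10 fell when adjusted over the list alone. The NRF2 list had median log2 -0.55, camera adjusted p = 0.000583 (down, adjusted p = 0.685 with estimated correlation). Members included Ugdh at -1.02 ± 0.17. In the xenobiotic list, 1 rose, 7 fell and 13 did not pass of 21, also when adjusted over the list alone, with Cyp2c29 at 2.04 ± 0.19 and Nr1i3 at -1.38 ± 0.16 (camera adjusted p = 0.0596, adjusted p = 0.689 with estimated correlation). It was called down after median-ratio scaling (adjusted p = 0.0170), quantile normalization (0.00724) and without iAMPK HFD+dox replicate 3 (adjusted p = 0.0106). For bile acid genes, 2 rose, 4 fell and 12 did not pass of 18, also when adjusted over the list alone, with Slc10a1 (0.82 ± 0.13) higher and Abcb4 (-0.71 ± 0.11) lower. Of the lysosome and autophagy genes, 2 rose, 5 fell and 27 did not pass of 34, and 3 rose and 5 fell when adjusted over the list alone, with the proton pump subunit Atp6v0d2 at -1.55 ± 0.24.

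Interferon genes that passed were lower in L-iAMPK HFD+dox than in iAMPK HFD+dox: 14 fell and 10 did not pass of 24, and 21 fell when adjusted over the list alone. The interferon list had median log2 -0.92, camera adjusted p = 6.23e-07 (down, adjusted p = 0.689 with estimated correlation). Members included the transcription factor Irf9 at -0.65 ± 0.11 and Oasl1 at -1.11 ± 0.21. In the extracellular matrix and stellate list, 1 rose, 7 fell and 26 did not pass of 34, and 1 rose and 20 fell when adjusted over the list alone (median log2 -0.65, camera adjusted p = 0.00011, adjusted p = 0.828 with estimated correlation), where Col15a1 rose by 1.22 ± 0.19 and Lrat was lower (-1.11 ± 0.22). For pericentral hepatocyte genes, 8 fell and 10 did not pass of 18, also when adjusted over the list alone. The pericentral list had median log2 -0.50, camera adjusted p = 0.0111 (down, adjusted p = 0.689 with estimated correlation). Members included Oat at -1.84 ± 0.24 and Rhbg at -1.51 ± 0.21. For hepatocyte markers, 7 rose, 2 fell and 15 did not pass of 24, 7 rose after median-ratio scaling, and 7 rose and 4 fell when adjusted over the list alone. The hepatocyte list had median log2 0.17, camera adjusted p = 0.00139 (up, adjusted p = 0.685 with estimated correlation). Members included Ahsg at 0.73 ± 0.11. Quantile normalization ended the list's call (adjusted p = 0.673). Macrophage markers (3 fell and 28 did not pass of 31, also when adjusted over the list alone) were called down (camera adjusted p = 0.0197, adjusted p = 0.868 with estimated correlation), a call that ended without iAMPK HFD+dox replicate 3 (adjusted p = 0.237) or L-iAMPK HFD+dox replicate 1 (0.273). Sinusoidal endothelial markers (1 fell and 15 did not pass of 16, and 3 fell when adjusted over the list alone) were called down (camera adjusted p = 0.0275, adjusted p = 0.828 with estimated correlation) until libraries were left out, the call ending without iAMPK HFD+dox replicate 2 (adjusted p = 0.0782), L-iAMPK HFD+dox replicate 1 (0.0640) or L-iAMPK HFD+dox replicate 2 (0.0625). The AMPK list was called up (camera adjusted p = 0.000592, adjusted p = 0.419 with estimated correlation), at adjusted p = 0.0435 without Prkaa1 (0.685 with an estimated correlation). Among acute-phase genes, 5 rose, 7 fell and 10 did not pass of 22, and 5 rose and 13 fell when adjusted over the list alone (camera adjusted p = 0.570, 0.0362 and down after quantile normalization), with Fgb at 1.06 ± 0.14 higher and Steap4 at -1.12 ± 0.16 lower.

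On doxycycline, 581 genes were higher and 1301 lower in L-iAMPK livers (limma), and 1034 and 915 after median-ratio scaling, with 1494 calls shared. The total of 1882 was 908 without iAMPK HFD+dox replicate 2, 1075 without replicate 3 of that group, and 1015, 1175 and 1190 without L-iAMPK HFD+dox replicates 1, 2 and 3. It was 4819 with array weights, 297 with a log2 change of at least 1 as well, and 1083 by edgeR on recovered reads. The authors' table has 1555 called genes for this pair (cutoff not given here), 629 higher and 926 lower in L-iAMPK HFD+dox. Of the 1416 tested, 1068 were called here in the same direction.

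Both comparisons called 295 genes higher, among them Muc13, Cux2 and Csad, and 963 lower, among them Acsf2, Abcc3 and Ces1g, while 3 genes moved in opposite directions. Independent lists of those sizes would share 27.6 higher and 274 lower genes. The comparisons share the L-iAMPK HFD+dox libraries, and 20 simulations with no effect gave an overlap of 0 at most, which does not measure what shared libraries add where effects are present. Fold changes correlated across genes at r = 0.732, against 0.502 in the simulations, and their covariance was 0.135 against 0.0205, a difference of 0.114. Part of the excess may come from the shared libraries, which are too few to split. After median-ratio scaling 677 genes were higher and 553 lower in both. The overlap of 1258 was 643 without iAMPK HFD+dox replicate 2, 776 without replicate 3 of that group, and 682, 752 and 783 without L-iAMPK HFD+dox replicates 1, 2 and 3. It was 3240 with array weights, 731 by edgeR, 793 with only the compared libraries in each fit, and 177 with a log2 change of at least 1 as well.

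Whether the response to doxycycline differed between the genotypes was tested as an interaction. The value of a gene is its change with doxycycline in L-iAMPK minus that in iAMPK livers. Sterol, matrix and macrophage genes that passed had negative values, which high levels in iAMPK HFD+dox or L-iAMPK HFD also give. The cholesterol, matrix and macrophage medians were 0.34, 0.26 and 0.62 for doxycycline in iAMPK and 0.82, 0.47 and 0.77 between genotypes without doxycycline. L-iAMPK HFD+dox was not compared with iAMPK HFD here. Among cholesterol synthesis and uptake genes, 13 fell and 11 did not pass of 24, 8 fell after median-ratio scaling, and 18 fell when adjusted over the list alone. The cholesterol list had median log2 -1.49, camera adjusted p = 8.43e-07 (down, adjusted p = 0.507 with estimated correlation). Members included Mvk at -1.86 ± 0.21 and Idi1 at -1.22 ± 0.23. Of the extracellular matrix and stellate markers, 15 fell and 19 did not pass of 34, and 32 fell when adjusted over the list alone. The matrix list had median log2 -1.07, camera adjusted p = 4.19e-07 (down, adjusted p = 0.507 with estimated correlation). Members included Col4a2 at -1.75 ± 0.32 and Lrat at -1.60 ± 0.32. For macrophage markers, 10 fell and 21 did not pass of 31, and 20 fell when adjusted over the list alone. The macrophage list had median log2 -1.31, camera adjusted p = 6.07e-06 (down, adjusted p = 0.517 with estimated correlation). Members included Mmp12 at -3.98 ± 0.77. Of the proliferation genes, 9 fell and 8 did not pass of 17, and 11 fell when adjusted over the list alone. The proliferation list had median log2 -0.97, camera adjusted p = 0.000891 (down, adjusted p = 0.507 with estimated correlation). Members included Ccnd1 at -2.89 ± 0.47 and Birc5 at -1.38 ± 0.23. For NRF2 targets, 8 fell and 11 did not pass of 19, 5 fell after median-ratio scaling, and 1 rose and 14 fell when adjusted over the list alone. The NRF2 list had median log2 -0.99, camera adjusted p = 0.00101 (down, adjusted p = 0.507 with estimated correlation). Members included Gsta4 at -1.39 ± 0.24. Of the hepatocyte markers, 3 rose and 21 did not pass of 24, 9 rose after median-ratio scaling, and 9 rose when adjusted over the list alone. The hepatocyte list had median log2 0.38, camera adjusted p = 1.7e-07 (up, adjusted p = 0.302 with estimated correlation). Members included Fgb at 1.13 ± 0.20, and quantile normalization ended that call (adjusted p = 0.185). Among fatty acid oxidation genes, 11 fell and 17 did not pass of 28, 3 fell after median-ratio scaling, and 14 fell when adjusted over the list alone (median log2 -0.43, camera adjusted p = 0.00531, adjusted p = 0.507 with estimated correlation). For sinusoidal endothelial markers, 6 fell and 10 did not pass of 16, 1 fell after median-ratio scaling, and 9 fell when adjusted over the list alone (median log2 -0.55, camera adjusted p = 0.00112, adjusted p = 0.510 with estimated correlation). For interferon genes, 3 fell and 21 did not pass of 24, and 12 fell when adjusted over the list alone (median log2 -0.76, camera adjusted p = 0.000891, adjusted p = 0.517 with estimated correlation). Oxidative phosphorylation was called up (median log2 0.03, camera adjusted p = 0.000342, adjusted p = 0.507 with estimated correlation) with 0 of 55 members passing in limma (4 at an unadjusted p under 0.05, 2 by edgeR) and 7 after median-ratio scaling. Quantile normalization ended the call (adjusted p = 0.124). Lipid droplet, lysosome and immediate-early lists were called down and the gluconeogenesis, bile acid, periportal, sex-biased and AMPK lists up (camera adjusted p from 0.000891 to 0.0424, and from 0.302 to 0.524 with an estimated correlation). The AMPK call ended without Prkaa1 (adjusted p = 0.0532). Median-ratio scaling ended the gluconeogenesis, periportal and sex-biased calls (adjusted p = 0.0958, 0.140 and 0.119), and quantile normalization these and the bile acid call (adjusted p = 0.384, 0.697, 0.187 and 0.104). Of the 18 list calls, 3, 2 and 1 ended without L-iAMPK HFD replicates 1 to 3 (adjusted p up to 0.0750, 0.0785 and 0.102). For L-iAMPK HFD+dox replicate 3 the count was 2 (up to 0.0820). For iAMPK HFD replicates 1 to 3 the counts were 2, 1 and 4 (up to 0.0931, 0.0750 and 0.122). For iAMPK HFD+dox replicates 1 to 3 they were 2, 1 and 5 (up to 0.0526, 0.0528 and 0.113). Slc10a1 (1.32 ± 0.18), Dgat2 (0.80 ± 0.15), Thrsp (1.44 ± 0.28) and Fbp1 (0.77 ± 0.16) had positive values, and Abcc3 (-3.55 ± 0.21), Rhbg (-2.26 ± 0.30), Krt23 (-2.48 ± 0.24), Il1rn (-2.52 ± 0.37) and Klf6 (-2.06 ± 0.37) negative ones, with limma adjusted p from 1.03e-05 to 0.0161.

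The interaction was higher for 254 genes and lower for 1409 in limma, and for 672 and 687 after median-ratio scaling, with 941 calls shared and a median log2 value of -0.15 over all genes. The total of 1663 was 633 without iAMPK HFD replicate 1, 2803, 527 and 783 without iAMPK HFD+dox replicates 1, 2 and 3, 561 and 589 without L-iAMPK HFD replicates 1 and 2, and 800, 976 and 844 without L-iAMPK HFD+dox replicates 1, 2 and 3. It was 4673 with array weights, 558 with a log2 change of at least 1 as well, and 736 by edgeR.

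Doxycycline without active AMPK was examined within iAMPK livers as a control comparison. No gene passed in limma, where 0 of 12614 reached the threshold and 786 had an unadjusted p under 0.05, and edgeR on recovered reads called 0 as well, with 741 at an unadjusted p under 0.05. The smallest p-values belonged to Ccnf, a cyclin F gene, at 5.06 ± 0.163 FPKM with and 9.21 ± 0.460 without doxycycline (-0.80 ± 0.12, adjusted p = 0.494), to Bcl2a1b (1.38 ± 0.23, adjusted p = 0.600) and to Arhgef26 (-0.98 ± 0.17, adjusted p = 0.604). Prkaa1 (-0.18 ± 0.14, adjusted p = 0.871) did not pass, and neither did Muc13 (-0.01 ± 0.14, adjusted p = 0.994) and Acsf2 (-0.12 ± 0.13, adjusted p = 0.899), which were chosen after their values with active AMPK were seen, nor did the other AMPK subunit genes (adjusted p from 0.811 to 0.963). With array weights 3 genes passed, among them Ccnf and Bcl2a1b (both at adjusted p = 0.0332).

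Camera nevertheless called 15 of the 29 lists in this comparison, 10 up and 5 down, and fry called 0. Macrophage markers had the smallest camera p (median log2 0.62, camera adjusted p = 8.3e-13), with Mmp13 at 1.11 ± 0.37 and Ccr2 at 1.09 ± 0.37, neither of which passed. Matrix, lymphocyte and endoplasmic reticulum stress genes were called up (median log2 0.26, 0.64 and 0.23, camera adjusted p = 9.99e-05, 0.000384 and 0.000201), the last not without iAMPK HFD+dox replicate 1 (adjusted p = 0.445). Oxidative phosphorylation genes were called down (median log2 -0.06, camera adjusted p = 2.04e-05). With an estimated correlation these 5 lists lay at adjusted p = 0.616. Also called up were the cholesterol, neutrophil, proliferation, sinusoidal endothelial, interferon and acute-phase lists (median log2 0.34, 0.55, 0.27, 0.18, 0.17 and 0.17, camera adjusted p = 0.000384, 0.0184, 0.0182, 0.0184, 0.0195 and 0.0139). The fatty acid oxidation, bile acid, xenobiotic and clock lists were called down (median log2 -0.07, -0.12, -0.08 and -0.15, camera adjusted p = 0.0182, 0.0298, 0.0206 and 0.00621). With an estimated correlation the latter 10 lists lay at adjusted p from 0.616 to 0.717. The bile acid and xenobiotic calls ended after median-ratio scaling (adjusted p = 0.0833 and 0.0737), and these and the fatty acid oxidation call after quantile normalization (adjusted p = 0.294, 0.235 and 0.317). Of the 15 list calls, 6, 3 and 4 ended without iAMPK HFD replicates 1 to 3 (adjusted p up to 0.863, 0.826 and 0.365). For iAMPK HFD+dox replicates 1 to 3 the counts were 2, 4 and 7 (up to 0.445, 0.171 and 0.831).

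The genotypes were also compared without doxycycline, where per the labels AMPK was active in neither. Cox7a1, a cytochrome c oxidase subunit of muscle, stood at 9.69 ± 2.28 FPKM in L-iAMPK HFD and 2.06 ± 0.866 in iAMPK HFD (2.02 ± 0.25, limma adjusted p = 0.00540). The cation channel gene Trpm4 was higher in L-iAMPK HFD (2.74 ± 0.457 against 0.452 ± 0.0890 FPKM, 1.76 ± 0.16, adjusted p = 0.00282), as was the immediate-early gene Egr1 (15.2 against 5.39, 1.42 ± 0.19, adjusted p = 0.00540). Car3, a carbonic anhydrase, was lower (522 ± 75.9 against 1799 ± 265, -1.78 ± 0.18, adjusted p = 0.00282), and so was Abcb11 (80.9 ± 5.90 against 116 ± 7.39, -0.52 ± 0.07, adjusted p = 0.00771). Npdc1 (1.60 ± 0.24), Mogat1 (1.94 ± 0.44) and Cystm1 (1.56 ± 0.32) were higher and Mup7 (-7.05 ± 1.35), Mup11 (-6.30 ± 1.53), Serpina1e (-4.86 ± 1.13), Mup12 (-4.38 ± 0.73) and Mup17 (-4.27 ± 1.02) lower, with adjusted p from 0.0101 to 0.0495. Leaving out a library ended calls among these 8 genes. The counts were 7 and 8 without L-iAMPK HFD replicates 1 and 2 (up to 0.168 and 0.163). For iAMPK HFD replicates 1 to 3 they were 7, 4 and 5 (up to 0.161, 0.0811 and 0.0762). By edgeR the calls of Mogat1, Mup7, Mup11, Mup12, Mup17 and Serpina1e ended (adjusted p = 0.0655, 0.0630, 0.108, 0.0502, 0.0673 and 0.0849). A fit of only the compared libraries ended those of Cystm1, Mup11, Mup12, Mup17 and Serpina1e (adjusted p = 0.0830, 0.0584, 0.0528, 0.0776 and 0.0626), and no filter on low values those of Mogat1, Mup11, Mup17 and Serpina1e (adjusted p = 0.0540, 0.0625, 0.0603 and 0.0546). Mup11 did not pass with median-ratio scaling or a pseudocount of 1 either (adjusted p = 0.0502 and 0.0521). Prkaa1 differed by 0.08 ± 0.14, adjusted p = 0.780, and the remaining AMPK subunit genes did not pass (adjusted p from 0.0705 to 0.929), except Prkab2 with array weights (adjusted p = 0.00675) and without L-iAMPK HFD replicate 3 (adjusted p = 0.0424).

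Sterol genes that passed were higher in L-iAMPK HFD than in iAMPK HFD: 4 rose and 20 did not pass of 24, 3 rose and 1 fell after median-ratio scaling, and 19 rose and 1 fell when adjusted over the list alone. The cholesterol list had median log2 0.82, camera adjusted p = 4.12e-06 (up, adjusted p = 0.451 with estimated correlation). Members included Mvk at 0.90 ± 0.15 and Tm7sf2 at 0.71 ± 0.12. For fatty acid oxidation, 6 rose and 22 did not pass of 28, 1 rose after median-ratio scaling, and 7 rose when adjusted over the list alone. The fatty acid oxidation list had median log2 0.20, camera adjusted p = 0.00151 (up, adjusted p = 0.451 with estimated correlation). Members included Acot2 at 1.38 ± 0.23. For bile acid genes, 1 rose, 5 fell and 12 did not pass of 18, and 1 rose and 7 fell when adjusted over the list alone. The bile acid list had median log2 -0.30, camera adjusted p = 1.23e-05 (down, adjusted p = 0.451 with estimated correlation). Members included Hsd3b7, an enzyme of bile acid synthesis, at -0.58 ± 0.11. For proliferation, 1 rose and 16 did not pass of 17, and 8 rose when adjusted over the list alone. The proliferation list had median log2 0.67, camera adjusted p = 0.000448 (up, adjusted p = 0.451 with estimated correlation). Members included Birc5 at 0.79 ± 0.17. Among hepatocyte markers, 1 rose and 23 did not pass of 24, 1 rose and 1 fell after median-ratio scaling, and 2 rose and 5 fell when adjusted over the list alone, and the list was called down (median log2 -0.21, camera adjusted p = 3.76e-05, adjusted p = 0.451 with estimated correlation) until quantile normalization (adjusted p = 0.0976). For fatty acid and triglyceride synthesis, 1 rose and 23 did not pass of 24, and 3 rose when adjusted over the list alone. The list was called up (median log2 0.73, camera adjusted p = 0.0105, adjusted p = 0.519 with estimated correlation), but not without L-iAMPK HFD replicate 2 (adjusted p = 0.120). For oxidative phosphorylation, 2 rose and 53 did not pass of 55, and 3 rose when adjusted over the list alone (median log2 0.11, camera adjusted p = 0.00323, adjusted p = 0.519 with estimated correlation). That call, up, ended after median-ratio scaling (adjusted p = 0.200) and without L-iAMPK HFD replicate 3 (adjusted p = 0.112). In the lysosome list 3 rose and 31 did not pass of 34, and 6 rose when adjusted over the list alone. It was called up (camera adjusted p = 0.0142, adjusted p = 0.519 with estimated correlation) but not without L-iAMPK HFD replicate 1 (adjusted p = 0.0815) or L-iAMPK HFD replicate 2 (0.0860). Immediate-early genes, with 1 higher among 14, and sinusoidal endothelial markers, with 2 among 16, were called up (median log2 0.76 and 0.25, camera adjusted p = 0.00647 and 0.0150, 0.456 and 0.519 with an estimated correlation). The endothelial call ended without iAMPK HFD replicate 2 (adjusted p = 0.292). After median-ratio scaling 0 members of the oxidative phosphorylation, lysosome and endothelial lists passed in limma (4, 11 and 3 at an unadjusted p under 0.05, 0 in each by edgeR). Pericentral genes, with 0 of 18 passing in limma (5 at an unadjusted p under 0.05, 0 by edgeR), and periportal genes, with 1 lower among 17, were called down (median log2 -0.22 and -0.19, camera adjusted p = 0.00134 and 0.00253, both at 0.451 with an estimated correlation). The periportal call ended after quantile normalization (adjusted p = 0.420). The endoplasmic reticulum stress list, with 0 of 20 passing in limma (6 at an unadjusted p under 0.05, 0 by edgeR), was called down (median log2 -0.05, camera adjusted p = 0.0453, adjusted p = 0.610 with estimated correlation). That ended after median-ratio scaling (adjusted p = 0.0853), quantile normalization (0.439) and without iAMPK HFD replicate 1 (adjusted p = 0.137), iAMPK HFD replicate 2 (0.0580), L-iAMPK HFD replicate 1 (0.211) or L-iAMPK HFD replicate 2 (0.170). Macrophage and matrix markers were called up (median log2 0.77 and 0.47, camera adjusted p = 1.26e-05 and 0.000142, both at adjusted p = 0.519 with an estimated correlation), with 0 of 31 macrophage markers passing in limma (19 at an unadjusted p under 0.05, 0 by edgeR). For sex-biased genes, 2 fell and 13 did not pass of 15, and 1 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.00416, adjusted p = 0.451 with estimated correlation, and adjusted p = 0.0509 after quantile normalization), the genes being Mup20 and Slco1a1 (limma adjusted p = 0.0230 and 0.0433). The xenobiotic list was called down with a median of 0.09 and a mean of -0.17, the acute-phase list with 0.02 and 0.17, and the list of blood, pancreas and fat markers with 0.10 and -0.29. Median-ratio scaling ended these 3 calls (adjusted p = 0.132, 0.299 and 0.0953), as did quantile normalization (adjusted p = 0.451, 0.958 and 0.123), and they lay at adjusted p = 0.451, 0.519 and 0.451 with an estimated correlation. They also ended without a library, the xenobiotic one without iAMPK HFD replicate 3 (adjusted p = 0.146) or L-iAMPK HFD replicate 1 (0.107), the acute-phase one without iAMPK HFD replicate 2 (adjusted p = 0.150), iAMPK HFD replicate 3 (0.0643) or L-iAMPK HFD replicate 3 (0.170), and the last without L-iAMPK HFD replicate 2 (adjusted p = 0.196). Of the 47 named genes called in this comparison, 5 (Abcb11, Car3, Cox7a1, Egr1 and Trpm4) passed with each of the 6 libraries left out. The others lost 41, 41 and 1 without L-iAMPK HFD replicates 1 to 3 (up to 0.168, 0.174 and 0.0694). For iAMPK HFD replicates 1 to 3 they lost 40, 26 and 26 (up to 0.161, 0.108 and 0.115). Birc5 did not pass by edgeR (adjusted p = 0.374), nor did Mvk and Hsd3b7 in a fit of only the compared libraries (adjusted p = 0.0568 and 0.0516).

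Without doxycycline, 384 genes were higher and 160 lower in L-iAMPK livers (limma), with a median log2 difference of 0.08 over all genes, and 193 and 253 after median-ratio scaling, with 348 calls shared. The total of 544 was 57, 288 and 223 without iAMPK HFD replicates 1, 2 and 3, and 38, 49 and 1444 without L-iAMPK HFD replicates 1, 2 and 3. It was 3078 with array weights, 358 by edgeR, 300 with only the compared libraries in the fit, and 109 with a log2 change of at least 1 as well.

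**Figure D3:**
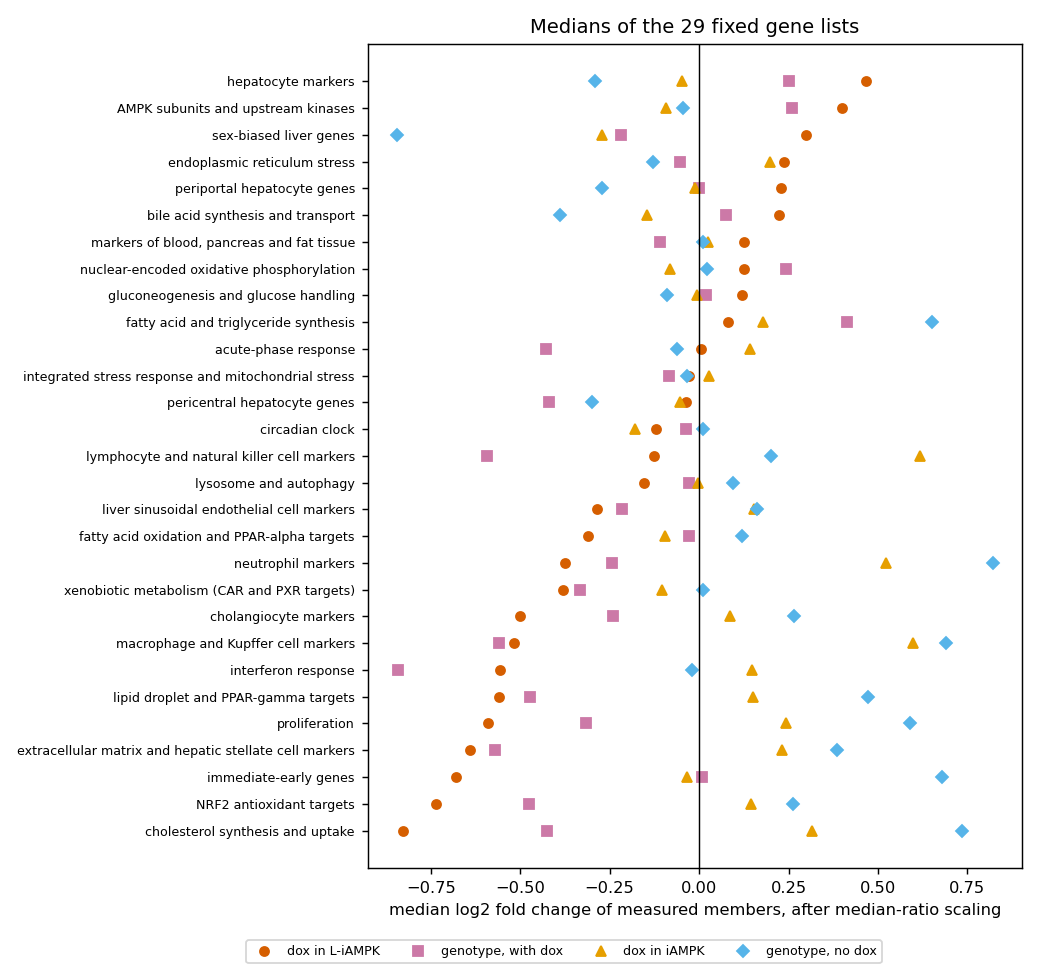
Median log2 change of the 29 fixed lists after median-ratio scaling for doxycycline in L-iAMPK, genotypes on doxycycline, doxycycline in iAMPK and genotypes without doxycycline. Each point is a list's median with no error bar. Cholesterol synthesis and matrix lists lie below 0 with active AMPK and above 0 in the control comparisons. The controls reuse L-iAMPK HFD and iAMPK HFD+dox with opposite sign, so these signs are not independent.

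The labels name the transgene ColA-AMPKa1 and give no position for it. Acsf2 and Abcc3 lie close together on chromosome 11, where Col1a1 lies too, and their surroundings were examined after their values were seen. Between 94343295 and 95076811 on chromosome 11 (mm10) lie 12 tested genes, Abcc3, Rsad1, Acsf2, Chad, Lrrc59, Eme1, Mrpl27, Xylt2, Col1a1, Ppp1r9b, Pdk2 and Itga3. All 12 were lower with doxycycline in L-iAMPK livers (10 after median-ratio scaling), and 9 were lower in both comparisons with active AMPK. Their median log2 change was -1.26 with doxycycline in L-iAMPK livers, -1.20 between genotypes on doxycycline, 0.02 with doxycycline in iAMPK livers and 0.08 between genotypes without doxycycline. In the control comparisons 0 passed for doxycycline in iAMPK and 1, Ppp1r9b (0.86 ± 0.21, adjusted p = 0.0435), between genotypes. Col1a1, a fibrillar collagen gene, changed by -1.86 ± 0.43, adjusted p = 0.0129, and Pdk2, a pyruvate dehydrogenase kinase, by -1.67 ± 0.11, adjusted p = 1.31e-05. Chad lies inside Acsf2 on the opposite strand, and the strand used in counting is not stated, so reads of the pair cannot be told apart.

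**Figure D4:**
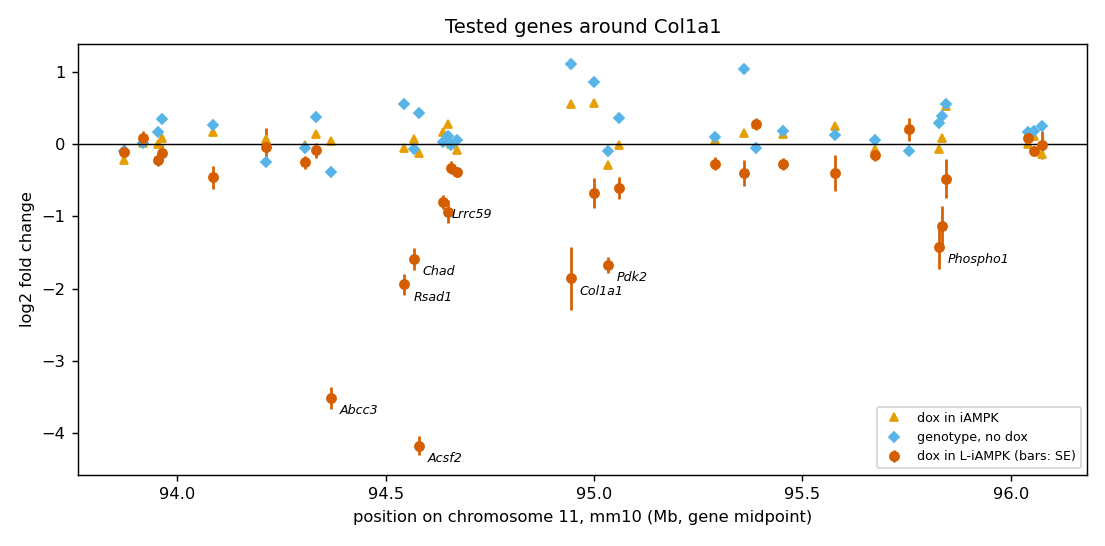
Log2 change of the tested genes around Col1a1 against position on chromosome 11 (Mb, mm10): points with SE bars for doxycycline in L-iAMPK livers, triangles for doxycycline in iAMPK livers and diamonds for genotypes without doxycycline. The 12 genes between 94343295 and 95076811 lie below 0 for doxycycline in L-iAMPK livers.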

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

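The tests on the chromosome 11 region, on the genotypes without doxycycline and on the cell markers and the edgeR test were chosen after those results were seen, and the splits of the libraries were planned beforehand.

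The doxycycline response differed between the genotypes for 1663 genes by limma's interaction test. The genes with the largest differences were Prkaa1 (8.24), Muc13 (5.57), Mup17 (5.03), Cyp2a4 (4.56), Cux2 (3.06), Cyp2c29 (2.68), Serpina3k (2.55), Lrit2 (2.44), Csad (2.41) and Mup3 (2.395), on the log2 scale. On the lower side they were Ly6d (-5.58), Sprr1a (-5.50), Lcn2 (-5.34), Ubd (-4.30), Saa2 (-4.25), Acsf2 (-4.05), Mmp12 (-3.98), Ces1g (-3.87), Ifi27l2b (-3.69) and Ttc39aos1 (-3.55). Calls of Mup17, Cyp2a4, Serpina3k, Mup3, Ly6d, Ubd and Ifi27l2b ended when a library was left out. The counts were 7, 7 and 2 without L-iAMPK HFD replicates 1 to 3 (up to 0.104, 0.101 and 0.0684). For L-iAMPK HFD+dox they were 5, 2 and 7 (up to 0.0991, 0.0767 and 0.0866). For iAMPK HFD they were 7, 2 and 2 (up to 0.0788, 0.0658 and 0.0842). For iAMPK HFD+dox they were 1, 7 and 6 (up to 0.0623, 0.102 and 0.105). By edgeR the calls of Cyp2a4, Ifi27l2b, Ly6d, Muc13, Mup3, Mup17 and Serpina3k ended (adjusted p = 0.133, 0.0562, 0.0792, 0.0644, 0.0986, 0.111 and 0.0717). No filter on low values ended those of Cyp2a4 and Mup17 (adjusted p = 0.0560 and 0.0597), pseudocounts of 0.1 and 1 those of Cyp2a4 and Mup17 in turn (adjusted p = 0.0706 and 0.0503), and quantile normalization that of Mup3 (adjusted p = 0.0688). Mup, Serpina, Cyp2a, Cyp2c, Ces1 and Saa genes share reads with close relatives.

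Of 100 splits of the 12 libraries, 1, the real one, gave as many interaction calls (1663, highest other 149), so chance can be excluded there. For the genes called in both comparisons with active AMPK, 1 of 100 splits, the real one, reached 1258. The highest other split (998) kept the 3 libraries with active AMPK together, as 4 of them did, and the highest among the rest gave 11. For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real and the highest other counts were 3259 and 2 for doxycycline in L-iAMPK (1 split as large), 1882 and 1 for genotypes on doxycycline (1), 544 and 3 for genotypes without doxycycline (1), and 0 and 7 for doxycycline in iAMPK (10).

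The 12 neighbouring genes around Col1a1 fell with doxycycline in L-iAMPK livers, and 9 of them, not Col1a1, Ppp1r9b and Itga3 (adjusted p = 0.0715, 0.223 and 0.325), were also lower than in iAMPK HFD+dox. Of 1000 shuffles of gene order, 0 held a run of 5 to 30 genes as dense in calls of both comparisons (binomial tail 1.15e-09, lowest shuffle 8.78e-08). That argues against chance runs only for independent genes, and Chad overlaps Acsf2 and Eme1 overlaps Lrrc59. A genotype difference present without doxycycline and doxycycline alone are argued against by medians of 0.0802 (quartiles over genes -0.02 and 0.46) and 0.0196 (-0.06 and 0.19), against -1.20 and -1.26 with active AMPK. AMPK activity and a local effect of a transcribed transgene cannot be told apart, because the labels name the transgene ColA-AMPKa1 without giving its position, which leaves open whether it lies at Col1a1, and distance from Col1a1 gave a rank correlation of 0.354 across 27 genes (permutation p = 0.0738).

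The genotypes differed in 544 genes without doxycycline. A transgene expressed at 10% or more of its induced level is argued against, since Prkaa1 differed by 0.0763 on the log2 scale (95% interval -0.24 to 0.39) where 4.85 would be needed. Calls confined to 1 linked region are argued against, with at most 1.29% (7) in any 2 Mb. Whether 1 library sets the result cannot be told apart from a genotype effect. The count was 38, 49 and 1444 without L-iAMPK HFD replicates 1, 2 and 3. Replicates 1 and 2 were the most alike pair within a group (chi-square per degree of freedom 7.93, against 55.7 and 55.5 with replicate 3). Distant effects of a linked region and mouse differences other than genotype stay open, untested.

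Of 34 matrix and stellate cell markers, 22 fell and 1 rose with doxycycline in L-iAMPK livers. The downward shift of all genes is argued against as the whole cause, since after median-ratio scaling 15 fell and the list's median was -0.64 (95% bootstrap interval over genes -0.81 to -0.46, from the spread between libraries -1.13 to -0.21). A smaller share of all non-hepatocyte cells and a change in stellate cells cannot be told apart: the stellate median lay -0.35 from the sinusoidal endothelial one (95% bootstrap interval over genes -0.57 to -0.15, from the spread between libraries -0.92 to 0.12), and the differences from macrophage (-0.12), cholangiocyte (-0.14), lymphocyte (-0.52) and neutrophil markers (-0.27) had intervals of both kinds that held 0. The stellate, endothelial and lymphocyte lists share no gene with another list, the macrophage, cholangiocyte and neutrophil lists share Gpnmb, Sox9 and Lcn2, and the most abundant stellate and endothelial genes stood at 93.1 (Dcn), 57.8 (Ecm1) and 46.5 (Bgn) mean FPKM against 39.7 (Clec4g), 27.6 (Fcgr2b) and 21.2 (Eng). Fewer or less active stellate cells, or fewer non-hepatocyte cells of all kinds, may account for it, as hypotheses not separated here.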

How the results depend on the processing

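The edgeR test, the list tests after quantile normalization and the AMPK list without Prkaa1 were chosen after seeing the data. With 3 libraries per group and 13569437 to 20696899 reads in genes, the interaction recovered 20.9% of simulated changes of log2 0.5, so smaller changes are often missed. Why values moved was not tested. A log2 change of at least 1 removes smaller changes, and edgeR (11 libraries) and fits of only the compared libraries have fewer samples. Among values for named genes, median-ratio scaling kept 579 on their side of the threshold, with 45 calls lost and 17 gained, and edgeR 539, with 95 lost and 7 gained. In the order doxycycline in L-iAMPK, genotypes on doxycycline, genotypes without doxycycline, interaction and both comparisons with active AMPK, array weights gave 5390, 4819, 3078, 4673 and 3240 genes (3 for doxycycline in iAMPK), and a log2 change of at least 1 gave 423, 297, 109, 558 and 177. Only the compared libraries gave 300 genes for genotypes without doxycycline and 793 for both comparisons. By edgeR the last 4 comparisons gave 1083, 358, 736 and 731 genes. An estimated correlation left 0 lists called in all 5 comparisons, and fry left 0 for doxycycline in iAMPK and 3 for genotypes without doxycycline. Oxidative phosphorylation turned down for doxycycline in L-iAMPK under fry (adjusted p = 0.715), and the acute-phase list turned up for genotypes without doxycycline after quantile normalization (adjusted p = 0.958).

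With each library left out, doxycycline in L-iAMPK ran from 1874 to 3417 genes, genotypes on doxycycline from 908 to 2442, doxycycline in iAMPK stayed at 0, genotypes without doxycycline ran from 38 to 1444, the interaction from 527 to 2803, and both comparisons from 643 to 1820. Lists called ran from 15 to 18, 9 to 14, 8 to 16, 15 to 19 and, for the interaction, 13 to 20. The replicate numbers were not taken to pair the libraries, since 8 of 18 same-numbered pairs, not each, had r over 0.1 (-0.275 to 0.446). As a hint from the data, 8 of 12 libraries correlated best with their own number, and the median r was 0.0790 for same-numbered and -0.0208 for other pairs. The replicate block gave 2919, 1626, 0, 404, 1431 and 1110 genes, and 18, 12, 16, 19 and 19 lists.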

Other observations

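The values here were chosen after they were seen. Mup7, a major urinary protein gene, stood at 1037, 46.4 and 99.9 FPKM in the libraries of iAMPK HFD, 426, 20.9 and 52.4 in iAMPK HFD+dox, 0.392, 0.215 and 2.81 in L-iAMPK HFD and 8.88, 0.868 and 3.52 in L-iAMPK HFD+dox. Slco1a1, an organic anion transporter, stood at 137, 68.5 and 41.9, 103, 17.9 and 21.4, 2.23, 1.80 and 15.2 and 61.5, 12.2 and 23.4 in the same order. Mup genes share reads with close relatives, so the value of a single Mup gene is uncertain.

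Some genes differed by genotype with and without doxycycline. Car3 stood at 1799 and 1576 FPKM in iAMPK livers without and with doxycycline, and at 522 and 616 in L-iAMPK livers. Cox7a1 stood at 2.06 and 3.17 against 9.69 and 11.1. Of the genes called in both genotype comparisons, 124 had the same direction (52 higher and 72 lower in L-iAMPK) and 46 the opposite one, where independent lists would share 17.7 higher and 16.5 lower genes. These comparisons share no libraries.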
